A study of Mus musculus with 22 samples.

How the data were processed

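Stranded mRNA libraries of 16 tissue samples (nonlesional skin and whole blood of the same 8 mice) and of 6 primary keratinocyte cultures were sequenced on an Illumina HiSeq instrument. The submitters' processing notes name STAR 2.5.2, HTSeq 0.6.1, DESeq2 with no version, and the genome build mm10. They do not give the role or order of these tools, the gene annotation, the strand setting or any filter. The values analysed were raw counts per gene symbol, deposited by the authors as one table of 24401 genes for the tissues and another of 21596 genes for the keratinocytes. All sample columns were used. The species of the transgene's coding sequence, and whether its reads counted toward Vgll3, are not given in the sources used here. Symbols were written in capitals, and 17763 of 26379 (67.3%) matched a mouse gene name of the reference annotation without regard to case; the rest were kept under the symbol given. Locations are those of the matched genes on mm10. RNA was isolated with a different kit for blood, skin and keratinocytes, so genotype effects of tissues were compared through their difference. Levels in skin and blood were also set side by side to judge abundance and the source of transcripts. Those comparisons hold no correction for the kit.

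Groups followed the labels: 4 transgenic and 4 wild-type libraries each for skin and for blood, and 3 and 3 for keratinocytes. The labelled sex was checked against Xist and 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty), and all 22 libraries matched. The 10 female libraries had 1065 to 20881 Xist counts and 0 to 20 counts on the Y-linked genes together, and the 12 male libraries 2 to 31 and 284 to 11681. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom of 4.87 to 735 over 30 pairs, so all libraries were kept as separate replicates. Total counts set the precision: a floor of 3 counts stands in for a group with none, and such floors cover counting error only, as do the exact binomial intervals given for folds of named genes against 1 to 3 counts in a group. In blood the 10 most abundant genes took 63.2% to 82.5% of the counts.

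Genotypes were compared in each tissue with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM normalization and the filterByExpr filter on low counts, with sex as a covariate in skin and blood and none in keratinocytes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM were computed over TMM-scaled library sizes. The sex-by-genotype term was tested within skin and within blood, and the tissue-by-genotype term over the 16 tissue libraries with animal as a block. Gene lists, 40 in number, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 if at least 3 members were measured, with an estimated correlation and with fry run beside it. Fry tests whether a list's genes move, on balance, one way, without comparing them with other genes. List scores are means of log2 CPM with a prior count of 2, compared by two-sided exact permutation tests that were added after the values were seen. Shared calls were set against the number that independent lists would share. Dixon's test looked for a library apart from the other 3 of its group (critical value 0.829), and its minimum mean of 1 CPM for named genes was set after a first run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

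The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from those said to be chosen or added later. The rule names Vgll3, Krt5 and Krt14 always. It then names the 6 genes with the highest and the 6 with the lowest log2 fold change among called genes whose groups do not overlap and whose higher group has a mean of at least 1 CPM, leaving out unnamed gene models, variable segments of antigen receptors and sex-linked genes. From each list it takes up to 3 called members with the smallest p, of which 2 to 4 are given as examples, and for interactions and overlaps the 4 genes with the smallest p in each direction. Where a list passed with fewer than 3 called members, the members with the smallest p were added as examples after their values were seen. Not every gene that the rule selects is reported.

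The procedure was tested on simulated data, drawn from a negative binomial distribution with each gene's observed mean and dispersion, in which 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold, and in each tissue the T cell list was shifted. The share of 4-fold changes recovered was 53.0% in skin, 72.7% in blood, 95.5% in keratinocytes and 27.3% for skin against blood. For 2-fold changes it was 7.46%, 17.9%, 65.7% and 0%, and for 1.5-fold changes 0%, 1.49%, 55.2% and 0%. Of all calls, 1 of 41, 5 of 69, 19 of 166 and 3 of 21 were false, and the T cell list had rank 1 among the lists in each tissue. Each gene was drawn independently, so the simulation cannot show how the list test behaves when genes are correlated. In the skin data the estimated correlation was 0.434 for T cell genes and 0.858 for MHC class I genes.

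Alternatives covered normalization (DESeq2 size factors, upper quartile), the count filter (none, or 1 CPM), the test (DESeq2 1.42.0, limma-voom, robust edgeR), thresholds (adjusted p under 0.1, a fold change of at least 2), the sex term, each sex alone, haemoglobin or Y-linked genes left out, animal number as a block and each library left out in turn. A hair follicle score as a covariate in skin, and leaving out skin-abundant genes in blood, were added after seeing the data.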

Results

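RNA sequencing was done on 22 mouse libraries. Nonlesional skin and whole blood came from 8 animals, 4 carrying the K5-VGLL3 transgene and 4 wild type, with 2 females and 2 males of each genotype. K5 stands for keratin 5, a protein of basal keratinocytes, and VGLL3 is a transcriptional cofactor that binds TEAD transcription factors. Primary keratinocytes came from the tails of 3 transgenic and 3 wild-type littermates aged 23 days and were cultured for 3 days. All 3 transgenic cultures were male by label, while 2 of the wild-type cultures were female and 1 was male. Total counts were 19600892 to 40678246 per skin library, 11197265 to 18235483 per blood library and 33412093 to 51877437 per keratinocyte library. Haemoglobin genes took 55.1% to 75.9% of the counts in blood and 0.00475% to 0.0438% in skin. The study's title concerns VGLL3, a factor with female-biased expression, and autoimmunity of the skin and of the whole body. The comparisons therefore ask how each tissue differed between transgenic and wild-type animals, and whether the difference depended on sex or tissue. Values are normalised read counts (CPM, over scaled library sizes), as mean ± SD, and log2 fold changes are transgenic minus wild type. Counts of list genes that rose or fell are of genes that passed over all genes.

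Vgll3 (chromosome 16, 65815257 to 65866368 on mm10) was 2.27-fold higher in transgenic keratinocytes. Its level was 461 ± 49.1 CPM (SD, n = 3) against 203 ± 19.1 CPM (SD, n = 3) in wild-type cultures, a log2 fold change of 1.19 (SE 0.098, edgeR adjusted p = 0.000716). In transgenic skin Vgll3 was 273 ± 337 CPM (SD, n = 4) against 64.5 ± 22.5 CPM (SD, n = 4), and the log2 fold change of 1.81 (SE 0.59) did not pass the edgeR test (adjusted p = 0.239). The transgenic skin libraries read 98.9, 778, 123 and 92.2 CPM, and the wild-type libraries 72.9, 92.4, 43.6 and 49.1 CPM. Without transgenic replicate 2 the log2 fold change of Vgll3 in skin was 0.85 (edgeR adjusted p = 0.105), and DESeq2 gave an adjusted p of 0.0258 with all 8 libraries. In blood Vgll3 had at most 16 counts in any library, with a log2 fold change of -2.13 (SE 0.878, edgeR adjusted p = 0.296). Krt5 and Krt14, which encode the keratin pair of basal keratinocytes, did not pass the test in skin (log2 fold changes 0.25 and 0.26, adjusted p = 0.615 and 0.523). In keratinocytes they did not pass either (-0.32 and 0.10, adjusted p = 0.089 and 0.554).

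**Figure D1:**
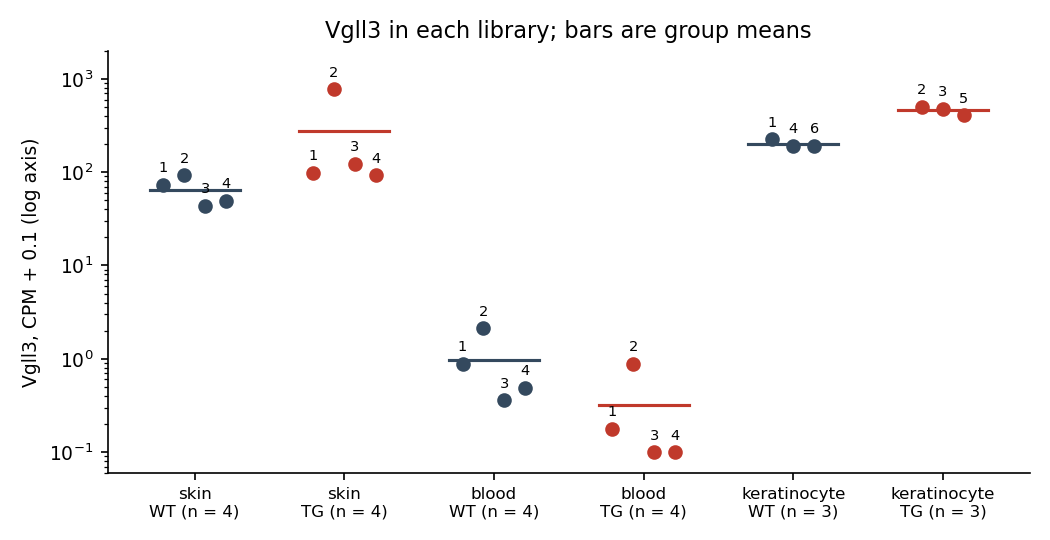
Vgll3 in each library, as CPM plus 0.1 on a log axis, for transgenic and wild-type skin, blood and keratinocytes; points are libraries and bars are group means. The 3 transgenic keratinocyte cultures lie above all 3 wild-type ones, and transgenic skin replicate 2 (778 CPM) lies above every other skin library.

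In nonlesional skin, 2 of 17901 genes passed the edgeR test, both higher in transgenic animals. Ccl17, a chemokine that attracts T cells through the receptor CCR4 (chromosome 8, 94810453 to 94812036), was 33.6-fold higher. Its level was 13 ± 7.33 CPM in transgenic skin against 0.351 ± 0.0795 CPM in wild type (n = 4 each, log2 fold change 5.07, SE 0.397, adjusted p = 0.0207). Tigit, an inhibitory receptor of T and NK cells (chromosome 16, 43648867 to 43664146), was 25.2-fold higher, at 2.29 ± 0.948 CPM against 0.0879 ± 0.0323 CPM (log2 fold change 4.66, SE 0.374, adjusted p = 0.0207). For both genes every transgenic library lay above every wild-type one. An unadjusted p under 0.05 was reached by 3035 genes, and the libraries of the 2 genotypes did not overlap in 7.41% of genes, where chance gives 2.86%. DESeq2 called 1100 genes, limma-voom 1 and edgeR without the sex term 0. The count was 0 without transgenic replicate 1 or 3 or wild-type replicate 1, 3 or 4, was 4 without transgenic replicate 2 or 4, and reached 278 without wild-type replicate 2.

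Gene groups of adaptive immunity stood higher in transgenic skin. Of the 40 gene lists, 23 passed the camera test with a preset inter-gene correlation of 0.01, 19 higher and 4 lower, and 0 passed with an estimated correlation. The higher lists were not all immune. Endothelium, sebaceous gland, matrix metalloproteinase and adipocyte lists also passed as higher, with median log2 fold changes of 0.46, 0.77, 0.37 and 0.28. Their camera adjusted p were 3.12e-05, 0.000153, 0.0043 and 0.0147, and 0.409, 0.487, 0.409 and 0.588 with an estimated correlation. The example genes given for the skin lists, other than Ccl17, did not pass over all genes and were chosen after their values were seen. All but 1 of the 21 T cell genes had a positive log2 fold change (median 1.34, camera adjusted p = 9.97e-21, and adjusted p = 0.187 with an estimated correlation). None of the T cell genes passed over all genes and 12 passed adjusted over the list alone. Foxp3, the transcription factor of regulatory T cells, had 8.29 ± 3.78 CPM in transgenic skin against 0.634 ± 0.399 CPM in wild type (adjusted p = 0.128). The lymphocyte surface receptors Cd5 and Cd6 had log2 fold changes of 1.92 and 2.93 (adjusted p = 0.115 each). Of 16 plasma cell and immunoglobulin constant genes, 14 were positive, with a median log2 fold change of 2.23 (camera adjusted p = 3.42e-18, and adjusted p = 0.146 with an estimated correlation). In that list 0 passed over all genes and 11 passed adjusted over the list alone. Jchain, the joining chain of polymeric antibodies, had 56.9 ± 35.0 CPM against 3.54 ± 1.17 CPM (adjusted p = 0.0832), and the kappa light chain gene Igkc had 305 ± 250 CPM against 13.3 ± 5.69 CPM (adjusted p = 0.102). Hair follicle genes moved with genotype in the same libraries: with each library's hair follicle score as a covariate, added after seeing the data, the medians of the T cell and plasma cell lists were 0.92 and 2.05.

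Antigen presentation and chemokine genes stood higher as well. All 15 MHC class I and antigen processing genes were positive (median 0.98, camera adjusted p = 5.72e-16, and adjusted p = 0.315 with an estimated correlation), and 13 of them passed adjusted over the list alone. Tap2, a subunit of the peptide transporter, had 99.6 ± 29.5 CPM in transgenic skin against 44.8 ± 5.12 CPM (log2 fold change 1.12, adjusted p = 0.157). All 19 interferon-gamma response and MHC class II genes were positive (median 1.10, camera adjusted p = 5.14e-15, and adjusted p = 0.312 with an estimated correlation), and 8 passed adjusted over the list alone. The interferon-induced GTPases Igtp and Gbp2 had log2 fold changes of 1.28 and 1.26 (adjusted p = 0.138 and 0.151). Of 33 interferon-stimulated genes 30 were positive, with a smaller median of 0.49 (camera adjusted p = 3.78e-07, and adjusted p = 0.409 with an estimated correlation). In the cytokine and chemokine list 29 of 30 genes were positive (median 1.26, camera adjusted p = 1.45e-12, and adjusted p = 0.146 with an estimated correlation), and 12 passed adjusted over the list alone. They included Cxcl13, which attracts B cells, at 80.1 ± 97.1 CPM against 3.4 ± 1.13 CPM (adjusted p = 0.131). Tnfsf13b, the B cell survival factor BAFF, had 5.39 ± 0.566 CPM against 2.09 ± 0.448 CPM (adjusted p = 0.115). The list of eosinophil and type 2 cytokine genes, which holds Ccl17, had 10 of 12 positive members (median 1.49, camera adjusted p = 6.58e-11, and adjusted p = 0.146 with an estimated correlation). Ccl11 (eotaxin) and Ccl22, another chemokine for CCR4, had log2 fold changes of 1.45 and 2.60 (adjusted p = 0.0832 and 0.151). Of 16 complement genes 15 were positive (median 0.57, camera adjusted p = 1.18e-05, and adjusted p = 0.315 with an estimated correlation), among them C3 at 1520 ± 570 CPM against 488 ± 255 CPM (adjusted p = 0.173). With the hair follicle score as a covariate the medians were 0.59 for MHC class I, 0.40 for the interferon-gamma response, 0.60 for cytokines, 0.94 for type 2 cytokine genes and 0.38 for complement.

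Hair follicle, melanocyte and cell cycle genes stood lower in transgenic skin, with large differences between libraries of the same genotype. Of 30 hair shaft and follicle genes 28 were negative, with a median log2 fold change of -5.91 (camera adjusted p = 9.65e-09, and adjusted p = 0.487 with an estimated correlation). The mean log2 CPM of that list was -1.03, 4.23, -0.79 and -0.76 in the transgenic libraries and 5.28, -0.93, 9.36 and 6.86 in the wild-type ones. Replicate 2 of each genotype therefore lay within the range of the other genotype. The first principal component, which held 54.4% of the variance among skin libraries, ordered replicate 2 of each genotype in the same way. All 10 melanocyte genes and all 26 cell cycle genes were negative (medians -2.90 and -1.36, camera adjusted p = 0.000162 and 5.36e-14, and adjusted p = 0.468 and 0.409 with an estimated correlation). The minichromosome maintenance gene Mcm2 had 25.7 ± 4.41 CPM against 54.3 ± 24.0 CPM (adjusted p = 0.223). Suprabasal differentiation genes, basal epidermis genes and Hippo pathway targets did not pass (medians 0.04, 0.20 and -0.03, camera adjusted p = 0.339, 0.902 and 0.865). With the hair follicle score as a covariate the melanocyte median was -0.06 (camera adjusted p = 0.864) and the cell cycle median -0.38 (camera adjusted p = 0.000515, and adjusted p = 0.637 with an estimated correlation). The suprabasal list then passed as lower, with a median of -0.93 and 0 of 27 genes positive (camera adjusted p = 4.11e-14, and adjusted p = 0.333 with an estimated correlation). In 7 of the 40 lists (T cells, plasma cells, MHC class I, interferon-gamma response, cytokines, type 2 cytokine genes and complement) the mean log2 CPM of every transgenic library exceeded that of every wild-type one. Each gave a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 allows, and 0.163 adjusted over the 40 lists.

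**Figure D2:**
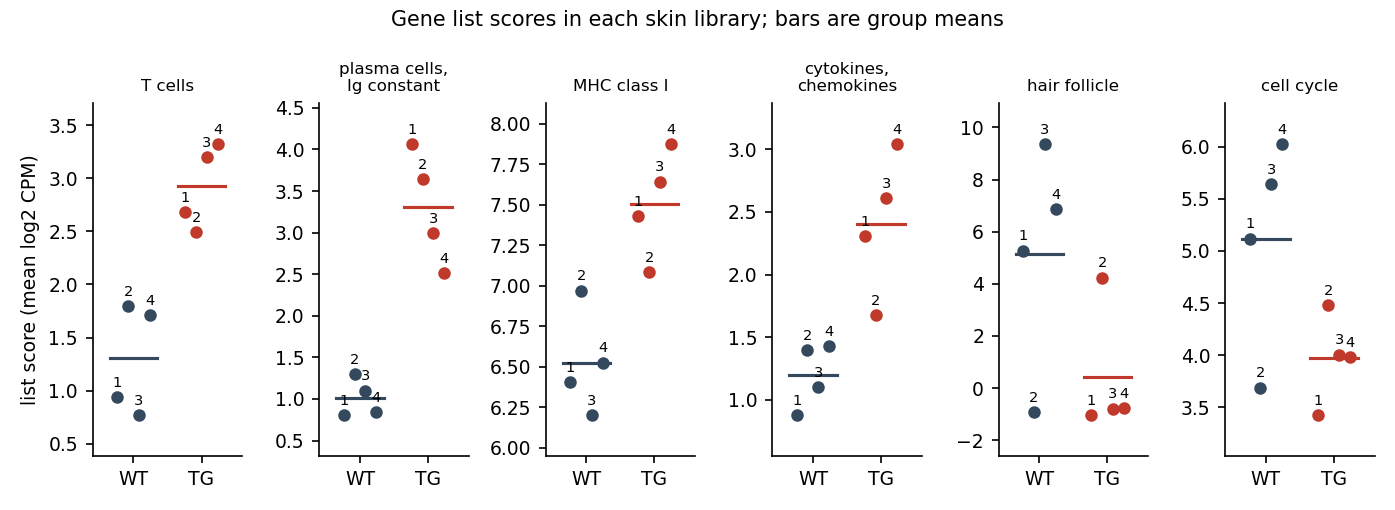
Mean log2 CPM of 6 gene lists in each skin library, transgenic and wild type, one point per library. The T cell, plasma cell, MHC class I and cytokine scores of the 4 transgenic libraries lie above those of all 4 wild-type libraries, whereas hair follicle and cell cycle scores overlap.

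In blood, 85 of 11174 genes passed the edgeR test, 24 higher and 61 lower in transgenic animals. No higher gene passed without transgenic replicate 1 or 3 or wild-type replicate 1, 2 or 4, 1 passed without transgenic replicate 4, and 58 passed without wild-type replicate 3. The higher genes included products of neutrophil granules and the neutrophil surface. Ngp, neutrophilic granule protein, had 477 ± 402 CPM in transgenic blood against 3.34 ± 4.25 CPM (n = 4 each, log2 fold change 7.22, SE 1.28, adjusted p = 0.0466). Cd177, a neutrophil surface glycoprotein, had 129 ± 96.7 CPM against 5.82 ± 2.64 CPM (log2 fold change 4.44, SE 0.692, adjusted p = 0.0335). Padi4, which citrullinates histones, was 6.0-fold higher (log2 fold change 2.59, adjusted p = 0.0429). Ltf (lactoferrin), named after its value was seen, completed the 4 called genes among 16 measured neutrophil genes, with a log2 fold change of 7.61. Its groups overlapped: the transgenic libraries had 713, 4.94, 213 and 692 CPM and wild-type replicate 3 had 5.84 CPM. All 16 were positive, 14 passed adjusted over the list alone, and the median log2 fold change was 3.31 (camera adjusted p = 2.40e-23, and adjusted p = 0.195 with an estimated correlation). Abca13, Lipg and Itgb2l rose by log2 fold changes of 7.46, 6.50 and 5.81, and Chil3, a chitinase-like protein of myeloid cells, by 3.53. Kcnn3 had 134 counts in the 4 transgenic libraries and 2 in the wild-type ones, 57.6-fold higher (95% counting interval 15.6 to 481). Of 19 monocyte and macrophage genes 18 were positive and 0 passed over all genes (median 0.78, camera adjusted p = 4.90e-06, and adjusted p = 0.297 with an estimated correlation). Of 32 interferon-stimulated genes 23 were positive and 0 passed (median 0.30, camera adjusted p = 0.00891, and adjusted p = 0.516 with an estimated correlation). The interferon-gamma response and MHC class II list, higher in skin, passed as lower in blood. There 11 of its 17 genes were negative and 0 passed (median -0.39, camera adjusted p = 0.0411, and adjusted p = 0.4955 with an estimated correlation).

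Lymphocyte genes were lower in transgenic blood. Of 21 T cell genes 20 were negative, 4 passed over all genes and 17 passed adjusted over the list alone, with a median log2 fold change of -0.85 (camera adjusted p = 1.63e-18, and adjusted p = 0.0694 with an estimated correlation). Cd3d and Cd3g, chains of the T cell receptor complex, had 9.15 ± 1.02 against 19.0 ± 2.87 CPM and 11 ± 1.65 against 21.2 ± 2.94 CPM (n = 4 each, edgeR adjusted p = 0.0243 and 0.0429). Trbc2, a T cell receptor constant gene named after its value was seen, fell by 1.22 on the log2 scale. These calls were not stable: 1 lower gene passed in all of blood when skin-abundant genes were left out, and 3 without transgenic replicate 3. All 16 B cell genes and all 12 NK cell genes were negative, with 0 past the threshold over all genes in either list (medians -0.56 and -0.64, camera adjusted p = 1.16e-06 and 8.32e-05, and adjusted p = 0.458 and 0.482 with an estimated correlation). Adjusted over the list alone, 2 B cell genes and 5 NK cell genes passed. Haemoglobin took 55.1% to 69.7% of the counts in transgenic blood and 60.7% to 75.9% in wild type, and the epidermal keratin Krt5, at 0.768 against 17.3 CPM, also moved with genotype in these libraries. Neutrophil genes rose there too (median log2 fold change 3.31). CPM are shares of the counts, so lower lymphocyte values do not by themselves show fewer lymphocytes or lower expression within them.

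Most of the genes lower in transgenic blood were more abundant in skin. Of the 61, 48 had a mean CPM in the skin libraries at least 10 times that in blood, and so did 1 of the 24 higher genes. Among all 11174 genes tested in blood, 3170 did. Krt5 had 0.768 ± 0.197 CPM in transgenic blood against 17.3 ± 7.38 CPM in wild type (log2 fold change -4.45, SE 0.376, adjusted p = 0.00366). Krt2, a keratin of the upper epidermis, had 0.0801 ± 0.0644 against 21.1 ± 13.8 CPM (log2 fold change -7.84, SE 0.751, adjusted p = 0.006). Of 15 suprabasal differentiation genes 13 fell, including Krt10 by 5.63 and Krtdap by 5.49 on the log2 scale (list median -4.13, camera adjusted p = 1.05e-35, and adjusted p = 0.0694 with an estimated correlation). Krt1 fell by 7.09. Krt36, Krt84 and Hrnr had 1, 3 and 1 counts in the 4 transgenic libraries and 153, 193 and 59 in the wild-type ones, 178-fold, 74.8-fold and 68.6-fold lower (95% counting intervals 31.5 to 7070, 25.2 to 366 and 11.8 to 2750). All 13 skeletal muscle genes were negative and 5 passed over all genes, including Acta1 at -2.99, Tnnt3 at -2.22 and the myosin heavy chain Myh4 at -4.10 (list median -2.11, camera adjusted p = 9.77e-20, and adjusted p = 0.0694 with an estimated correlation). Of 13 basal epidermis genes 10 were negative (median -0.80, camera adjusted p = 3.84e-13, and adjusted p = 0.220 with an estimated correlation), and 4 passed over all genes: Krt5, Krt14, Krt15 and Col17a1. Of 14 fibroblast and collagen genes, Postn and Lum fell by 4.26 and 3.11 (median -1.83, camera adjusted p = 3.29e-06, and adjusted p = 0.381 with an estimated correlation). The stress and wound keratinocyte list passed as lower (camera adjusted p = 0.00827, and adjusted p = 0.220 with an estimated correlation) with a mean of -0.91 but a median of 0.185. Cytl1 had 0 counts in the 4 transgenic libraries and 75 in the wild-type ones, at least 29.1-fold lower with a floor of 3 counts over the group.

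**Figure D3:**
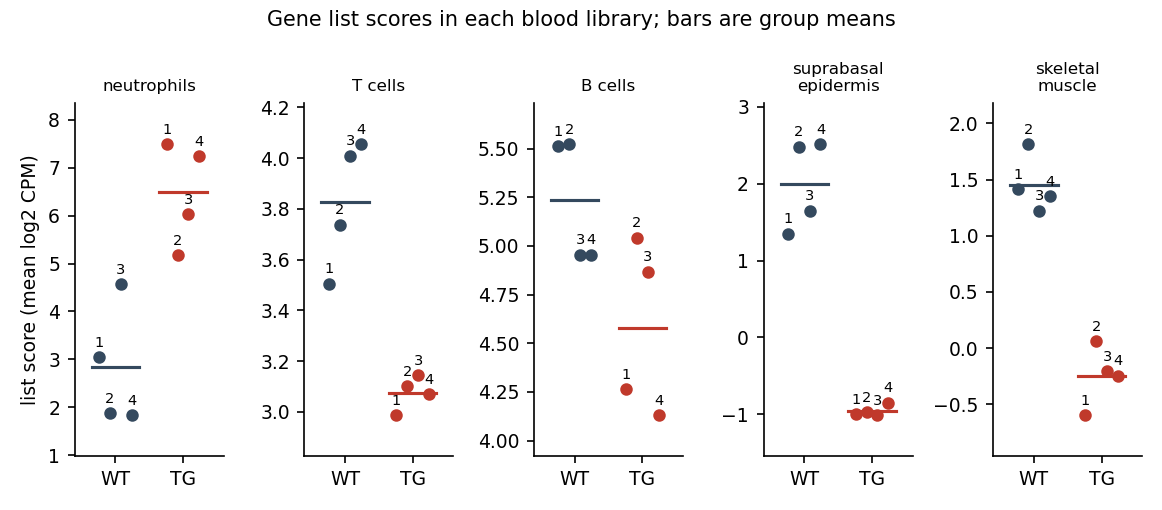
Mean log2 CPM of 5 gene lists in each blood library, transgenic and wild type, one point per library. Neutrophil scores of the 4 transgenic libraries lie above those of all 4 wild-type libraries, and T cell, suprabasal and muscle scores lie below.

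In total 14 lists passed in blood, 3 higher and 11 lower, and 0 passed with an estimated correlation. An unadjusted p under 0.05 was reached by 1730 genes, and 8.75% of genes did not overlap between genotypes, where chance gives 2.86%. The gene count was 1101 with no filter on low counts (836 higher, 265 lower), 451 with DESeq2 (315 higher, 136 lower), 21 with limma-voom (3 higher, 18 lower), 136 without the sex term (67 higher, 69 lower) and 1, a lower gene, when skin-abundant genes were left out. It was 10 without transgenic replicate 1 or wild-type replicate 4, 611 without transgenic replicate 2 (381 higher, 230 lower), 3 without transgenic replicate 3, 12 without transgenic replicate 4, 22 or 13 without wild-type replicate 1 or 2, and 112 without wild-type replicate 3 (58 higher, 54 lower).

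In cultured keratinocytes, 2197 of 14451 genes passed the edgeR test, 1028 higher and 1169 lower in transgenic cultures, 509 of them by at least 2-fold. The largest increases included genes of the prolactin and pregnancy-specific glycoprotein families. Prl8a9 had 51.0 ± 18.5 CPM against 0.576 ± 0.31 CPM (n = 3 each, log2 fold change 6.45, SE 0.451, adjusted p = 0.000485). Prl8a1 rose by 5.23 and Psg18 by 5.43 on the log2 scale. The adhesion receptor Adgrg7 rose by 5.65, the lymphatic growth factor Vegfc by 5.15 and the NADPH oxidase Nox4 by 5.01. Plekhs1 had 2.24 ± 0.204 CPM against 26.8 ± 4.71 CPM (log2 fold change -3.57, SE 0.157, adjusted p = 9.12e-05). Eprn, the glutamate transporter Slc1a1, Ccdc68, Adamts20 and Btn1a1 fell by 3.57, 3.52, 3.47, 3.42 and 3.17. Among neutrophil genes Padi4 rose by 2.48, and Ltf had 0 counts in transgenic cultures against 60 in wild type, at least 19.6-fold lower with a floor of 3 counts over the group. Tslp, a cytokine of epithelial cells that acts in type 2 immunity, had 1860 ± 366 CPM against 974 ± 160 CPM (log2 fold change 0.94, SE 0.169, adjusted p = 0.0122). Its list, of eosinophil and type 2 cytokine genes, did not pass (camera adjusted p = 0.386), and 4 of the 5 measured genes were negative.

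Cell cycle, sterol and chemokine genes were lower in transgenic keratinocytes, and complement and antigen presentation genes were higher. All 26 cell cycle genes were negative, 22 passed over all genes and 25 passed adjusted over the list alone (median -0.51, camera adjusted p = 6.75e-17, and adjusted p = 0.504 with an estimated correlation). The mitotic kinase Cdk1 had 101 ± 14.9 CPM against 170 ± 3.63 CPM (adjusted p = 0.00344), and Mcm6 and Rrm2 fell by 0.47 and 0.46 on the log2 scale. Of 21 sterol biosynthesis genes 20 were negative and 8 passed over all genes, among them Insig1 at -0.89 and Sc5d at -0.57 (median -0.48, camera adjusted p = 3.34e-06, and adjusted p = 0.670 with an estimated correlation). In the cytokine and chemokine list 9 of 22 genes fell and 2 rose (median -0.33, camera adjusted p = 7.34e-08, and adjusted p = 0.459 with an estimated correlation). The neutrophil-attracting chemokines Cxcl3 and Cxcl2 fell by 2.07 and 2.15, and Ccl20 fell by 2.53. The 2 that rose, named after their values were seen, were Ccl27a (1.07) and Il23a (1.46). Of 5 complement genes 4 rose (median 1.02, camera adjusted p = 7.41e-06, and adjusted p = 0.504 with an estimated correlation). C1s1, a protease of the classical pathway, had 119 ± 37.2 CPM against 28.2 ± 2.19 CPM (adjusted p = 0.00191), and C3 and C1ra rose by 1.02 and 0.79. C3ar1 had 83 counts in transgenic cultures and 1 in wild type, 84.8-fold higher (95% counting interval 14.8 to 3390). Of 15 MHC class I genes 5 rose (median 0.21, camera adjusted p = 0.000384, and adjusted p = 0.549 with an estimated correlation), with Nlrc5, a transactivator of MHC class I genes, at 5.03 ± 1.11 CPM against 0.821 ± 0.144 CPM. Of 13 interferon-gamma and MHC class II genes 3 rose and 1 fell (median 0.37, camera adjusted p = 0.0488, and adjusted p = 0.504 with an estimated correlation). The risers were Cd74, H2-Aa and H2-Ab1, at 2.62, 2.32 and 2.21, and Cxcl10, named after its value was seen, fell by 1.43. Monocyte and macrophage scores lay higher in transgenic cultures without overlap (1.471 to 1.988 against 0.91 to 1.187), and T cell scores lower (0.606 to 1.066 against 1.375 to 1.605). Neither list passed (camera adjusted p = 0.0831 and 0.0755). Each rests on 6 measured genes, and 3 of the T cell genes were positive and 3 negative, with 1 called. Of the 40 list scores, 9 lay higher and 9 lower without overlap, where chance gives 10% of lists. Each of these gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows, and 0.222 adjusted over the 40 lists. Cell types in the cultures were not measured, so a difference in them cannot be told apart from a change within keratinocytes. Col7a1, Itga6 and Col17a1, which anchor the epidermis to the dermis, rose by 1.67, 0.82 and 0.65, while the basal epidermis list did not pass (camera adjusted p = 0.0772). Of 22 Hippo pathway targets 4 rose and 6 fell, with Ptpn14, Arhgef17 and Asap1 falling by 0.69, 0.68 and 0.74 (camera adjusted p = 0.761).

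**Figure D4:**
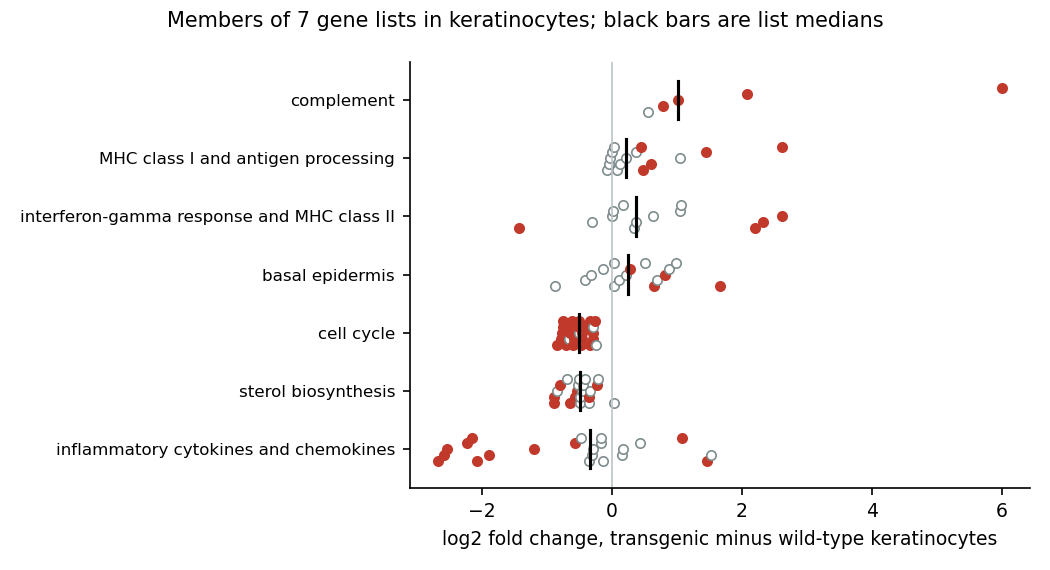
Log2 fold changes, transgenic minus wild type, of the members of 7 gene lists in keratinocytes; filled points have an adjusted p under 0.05 and black bars are list medians. All 26 cell cycle genes lie below 0 and all 5 complement genes lie above it.

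Of the 40 lists 36 could be tested in keratinocytes and 9 passed, 4 higher and 5 lower, with 0 past the threshold under an estimated correlation. Libraries of the 2 genotypes did not overlap in 36.3% of genes, where chance gives 10%. Sex was nearly confounded with genotype: with sex as a covariate, which rests on 1 wild-type male, 556 genes passed, and the 2197 genes had a median ratio of log2 fold changes of 0.997 to those without it. The gene count was 183 in male cultures alone (3 against 1). It was 3651 without transgenic replicate 5, 1084 and 1050 without transgenic replicates 2 and 3, and 1231, 880 and 1345 without wild-type replicates 1, 4 and 6. With sex as a covariate the cytokine list median was -0.60 in place of -0.33, and the MHC class I median 0.34 in place of 0.21.

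Whether the genotype effect differed between females and males was tested by the sex-by-genotype term. In skin 0 of 18726 genes passed with edgeR and 0 with limma-voom, while 1579 had an unadjusted p under 0.05. The genes with the smallest p among those with a larger log2 fold change in females were Sema3d (1.65), Hsd11b1 (1.74), Tdo2 (2.77) and Cldn5 (1.38), and among those with a smaller one Zp2 (-8.50), Rims1 (-4.72), Sfrp1 (-1.58) and Hbb-bs (-2.53). None of these 8 differences passed (adjusted p = 0.555 each). In blood 0 of 11778 genes passed with edgeR and 0 with limma-voom, 361 had an unadjusted p under 0.05, and 332 passed with no filter on low counts, 331 negative and 1 positive. The blood genes with the smallest p were Nxpe4 (1.46), Itgav (1.23) and the gene model AC111067.4 (1.32), besides a clone-named gene model (1.83), in the positive direction. In the negative direction they were Lifr (-2.11), the chemokine Ccl5 (-1.71), Tppp3 (-2.60) and complement C5, encoded by Hc (-11.02). Other genes of the liver, named after their values were seen, also had negative differences that did not pass, such as Alb (-10.16), Fgb (-13.82) and Ttr (-8.85). Each of these 3 and Hc was highest in transgenic replicate 2, a male, where Alb had 905 CPM against at most 147 CPM in the other blood libraries. Fitted alone, the skin of females gave 1170 calls and that of males 0, with 2 animals per genotype in each. Both female transgenic skin libraries had low hair follicle scores (-0.79 and -0.76) and both female wild-type ones high scores (9.36 and 6.86), whereas male scores were mixed.

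The genotype effect differed between skin and blood for 215 of 17803 genes (edgeR with animal as a block), more positive in skin for 167 and more negative for 48. The beta-defensin Defb6 differed by 4.95 (SE 0.367, adjusted p = 0.00114), with log2 fold changes of 0.78 in skin and -3.85 in blood. The hemidesmosome collagen Col17a1 had 0.24 in skin and -4.15 in blood, and Krt15 had 0.64 and -4.39. The serine protease inhibitor Serpina3j had 2.40 in skin, and in blood 1 count in transgenic libraries against 53. Of the 167 genes 37, these 4 among them, belong to the skin and muscle transcripts found in wild-type blood, and 109 were at least 10 times more abundant in skin than in blood libraries, as were 21 of the 48. How many of all 17803 tested genes were so abundant in skin was not counted, so the 109 and 21 do not show an excess. In the negative group Mapk13, a p38 kinase, had -0.08 in skin and 3.20 in blood, a difference of -3.02 (SE 0.407, adjusted p = 0.00878). The copper transporter Atp7a had -1.39 and 0.91. Csdc2, not tested in blood alone and with 6 and 1 counts there in transgenic and wild-type libraries, differed by -6.30, and the gene model RP24-499A8.6 by -6.05.

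Neither of the 2 skin calls, Ccl17 and Tigit, was among the genes tested in keratinocytes or blood, so no shared call with skin was possible. DESeq2 called 1100 genes in skin, where edgeR called 2. With DESeq2 in place of edgeR, 70 genes were higher in both skin and keratinocytes, where independent lists would share 29.8. They included Adgrg7, C1ra, C1s1 and C3, named after their values were seen. In the lower direction 113 were shared, where independent lists would share 34.9, among them the cell cycle genes Aurka, Ccna2 and Ccnb1. In skin the median of the cell cycle list was -1.36, and -0.38 with the hair follicle score as a covariate. How far the shared lower calls follow hair follicle content was not tested. Skin and blood shared 29 higher and 3 lower calls by DESeq2, against 11.8 and 2.61 for independent lists. Genes are not independent replicates, so these expectations are a yardstick and not a test across animals. Of 2135 keratinocyte calls measured in skin, 58.1% had the same sign there. Across genes, which are not independent, log2 fold changes correlated with a Pearson r of 0.0964 between skin and keratinocytes and 0.0235 between skin and blood.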

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

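The tests of tissue source, haemoglobin, hair content, blood left in skin, swapped labels and hair growth phase were chosen after the results were seen; the counts of other sample splits were planned. Dixon's test set 15 of 214 values (7.01%) apart from the other 3 libraries of their group, where chance gives about 1 in 20. Vgll3 in skin of transgenic replicate 2 was 778 CPM, against 92.2 to 123 in the others. The same library had list scores (mean log2 CPM) apart from its group for mast cells (1.264), lupus-associated genes (4.304), suprabasal differentiation (5.33) and hair follicle (4.233). In skin the adipocyte score of transgenic replicate 4 was 7.658, and the melanocyte score of wild-type replicate 2 was 2.607. In blood, transgenic replicate 2 stood apart in plasma cell genes (3.851), melanocyte genes (-0.636) and mitochondrially encoded genes (9.44). Stress and wound keratinocyte genes set transgenic replicate 3 (1.202) and wild-type replicate 3 (2.484) apart in blood. Wild-type blood replicate 4 stood apart in gamma-delta T cell genes (1.716) and progenitor genes (1.364), and wild-type blood replicate 2 in platelet genes (7.34).

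By the tissue-by-genotype test, 215 genes had a genotype effect that differed between skin and blood. The skin minus blood differences were 4.948 for Defb6, 8.702 for Serpina3j, 4.408 for Col17a1, 4.997 for Krt15, -3.019 for Mapk13, -2.337 for Atp7a, -6.054 for RP24-499A8.6 and -6.301 for Csdc2. Chance was argued against for this count: of 35 splits of the 8 animals 1, the real one, gave as many genes, and the highest other gave 145. It was not excluded, since 1 of 35 is the smallest share possible and the split tests were not adjusted for their number. The splits do not settle the source of this count. Of the 167 genes more positive in skin, 37 (Defb6, Serpina3j, Col17a1 and Krt15 among them) are skin-type and muscle transcripts of wild-type blood, whose source stays open below. Of the same 167 genes, 109 are far more abundant in skin than in blood, as are 21 of the 48 genes more negative in skin. The share of such genes among all genes tested was not counted, so these counts do not show an excess. Serpina3j and Csdc2 each had 1 count in 1 genotype in blood.

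Chance could not be excluded for the counts in skin or blood alone. In skin 2 of 34 splits gave as many genes as the real 2, and the other gave 2812, with transgenic replicates 1, 3 and 4 and wild-type replicate 2 against the rest, which points to a structure of the samples that follows hair follicle scores. For skin lists 7 of 34 splits gave as many as the real 23, with 29 as the highest other. In blood 2 of 34 splits gave as many genes as the real 85, the other giving 259 with transgenic replicates 1, 3 and 4 and wild-type replicate 3 together. For blood lists 10 of 34 splits gave as many as the real 14, with 17 as the highest other. In each tissue the split that follows sex could not be fitted. The 10 splits of the keratinocyte cultures are too few for a share under 0.05: 1 gave as many genes as the real 2197, with 0 in the highest other, and 4 gave as many lists as the real 9, with 16 in the highest other.

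Wild-type blood held skin-type and muscle transcripts that transgenic blood nearly lacked. The ratios of blood to skin given here compare levels from different RNA kits, without a correction for the kit. A loss of counts to haemoglobin was argued against: genes other than haemoglobin took more of the counts in transgenic blood (mean 37.3%) than in wild type (29.4%), and as shares of all counts 51 called genes of skin or muscle were at least 2.12-fold higher in wild type, where haemoglobin shares allow at most 1.3-fold. Tissue or reads of the skin sampled here were argued against for Krt2, whose lowest wild-type blood value was 1.29 times its highest value in any skin library (9.19 to 35.1 CPM in blood, 1.28 to 7.11 in skin); Krt6b (0.578 to 1.9 CPM) also lay above its wild-type skin mean of 0.164, but below 1 transgenic skin library (12.4). For the others this source stays open. Of these 51 genes 6 (11.8%) lay over 10-fold from the median ratio of wild-type blood to skin, 0.5%. That share lies between the limits of 10% set for a common source and 25% set against it. It cannot decide, because it depends on how the set was made. Krt36 and Krt84, at 20.1% and 12.5%, were added by name and are among the 6, and without them the share falls below 10%. Other genes could enter by being at least 10 times more abundant in skin, which bounds their ratio in advance. Tissue of another body site, taken up when blood was drawn, is a candidate source that cannot be told apart from an effect of the genotype, because it would follow genotype as well (the lowest wild-type Krt5 was 10.6 times the highest transgenic one).

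Immune gene lists were higher in transgenic skin, 15 in all. For 6 of them, each taken singly, hair follicle content as the whole cause was argued against. These were T cells, plasma cells, MHC class I, interferon-gamma response, cytokines and type 2 cytokine genes. With the hair score as a covariate the genotype effect on each score was at least 2.82 times its SE (95% limit 2.78, 4 residual degrees of freedom). The lowest was interferon-gamma, 1.12 ± 0.33 (SE) before and 0.60 ± 0.21 after, which passed the limit only narrowly. These 6 lists were grouped after the results were seen, as those of the 15 that exceeded the limit. That all 6 exceed it was therefore fixed by the grouping and is no further test. The limit was not adjusted for the number of lists. With the covariate and an estimated correlation none of the 6 passed camera (adjusted p = 0.0999 to 0.332). For the other 9 lists hair content and genotype cannot be told apart with 8 libraries, the effect being at most 2 times its SE; it did not shrink for interferon-stimulated genes (0.46 ± 0.19 before, 0.53 ± 0.27 after) or neutrophils (0.93 ± 0.65 before, 1.5 ± 0.8 after), which like lupus-associated and complement genes still passed the camera test (but not with an estimated correlation, adjusted p = 0.434, 0.332, 0.423 and 0.332), while B cells, gamma-delta T cells, NK cells, monocytes and dendritic cells no longer passed, their medians moving from 1.04, 0.67, 0.77, 0.54 and 0.67 to 0.27, -0.21, 0.15, 0.02 and 0.25. Blood left in the skin, at most 0.0289% by haemoglobin, would bring at most 3.96% of the rise of genes (list medians) in 14 lists, which argues against it there, but 12.2% for neutrophils, where it stays open as part of the rise; haemoglobin itself was 1.93 times as high in transgenic as in wild-type skin in males and 0.364 times in females. An effect of the genotype remains open as a hypothesis, as do differences between individual animals, since chance was not excluded.

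Skin replicate 2 of each genotype lay on the side of the other genotype in hair follicle genes. Swapped labels of these 2 libraries were argued against by Vgll3, which in transgenic replicate 2 was 10.7 times the highest of the other wild-type skin libraries. Vgll3 of wild-type replicate 2 (92.4 CPM) alone would allow a swap, and immune lists were mixed, with transgenic replicate 2 above wild-type replicate 2 in 9 of 16 and below in 7. The hair growth phase of the sampled skin is a candidate explanation: both of 2 further lists, melanocytes and cell cycle, placed transgenic replicate 2 highest of its group and wild-type replicate 2 lowest of its group. The labels give no hair growth phase, this pattern was taken up in place of keratinocyte sex after results were seen, and no biological explanation by genotype was tested for it.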

How the results depend on the processing

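The hair score covariate in skin and leaving out skin-abundant genes in blood were chosen after seeing the data. Of the counts under alternatives, 70 stayed within 1.5 times the main count and 47 did not. Of named gene values 3278 kept their direction and their side of the threshold, 548 kept direction but missed it, 136 came to pass it and 3 changed sign: Krt5 (-0.054) in skin of males only, and with the hair score covariate Prf1 (-0.157) and Krtap4-2 (0.125). None of these 3 had passed.

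The skin gene count of 2 became 1100 with DESeq2, 1 with limma-voom, 0 without the sex term, 0 with the animal number as a block, 1170 in females only, 0 in males only, 5 with the hair score covariate, and 0 to 278 with each library left out. The labels do not say whether the numbers 1 to 4 pair animals, which were treated as unpaired: correlations of pairs of the same number, after removing group means, were 0.082, -0.464, -0.116 and 0.077 in skin and 0.407, -0.041, -0.249 and -0.143 in blood, where 76 genes passed with the block. The blood gene count of 85 became 1101 with no filter, 451 with DESeq2, 21 with limma-voom, 136 without the sex term, 0 in females only, 0 in males only, 1 without skin-abundant genes, and 3 to 611 with each library left out. The keratinocyte gene count of 2197 became 509 with a fold change of at least 2, 556 with sex as a covariate, 183 in males only, and 880 to 3651 with each library left out. The list counts of 23, 14 and 9 in skin, blood and keratinocytes all became 0 with an estimated correlation; with fry they were 4, 3 and 11, and 9 blood lists passed without skin-abundant genes. With no filter 332 genes passed the sex-by-genotype test in blood, and by DESeq2 183 genes were shared by skin and keratinocytes and 32 by skin and blood. Single-sex and leave-one-out counts rest on fewer samples, and the fold minimum removes small changes by construction. With sex as a covariate the wild-type side rests on 1 male. Folds of the 2197 keratinocyte genes, selected without that covariate, then had a median ratio of 0.997 to those before. List medians moved from -0.33 to -0.60 for cytokines, from -0.48 to -0.63 for sterol biosynthesis and from 0.21 to 0.34 for MHC class I. They moved little for cell cycle (-0.51 to -0.53) and complement (1.02 to 0.99). For the other counts the cause was not tested. Where 1 wild-type male culture stands alone, it is assumed to vary like the other group. Recovery was limited: 7.46% of simulated 2-fold changes were recovered in skin, 17.9% in blood and 65.7% in keratinocytes. The simulation did not vary depth or spread within a tissue.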

Other observations

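The tests of symbol families were chosen after the results were seen. Gene families, taken as symbols with a common stem and at least 5 measured members, were tested in keratinocytes by Fisher's exact test, 816 tests over 408 families, of which 6 passed. Genes are not independent replicates. Minichromosome maintenance genes were lower, with 8 of 10 Mcm genes called (adjusted p = 0.000123), such as Mcm7 (-0.51) and Mcm10 (-0.46) on the log2 scale. Cxcl chemokines were lower in 6 of 8 (adjusted p = 0.00488), with Cxcl5 at -2.58 and Cxcl1 at -1.20. Claudins, which form tight junctions, were lower in 5 of 7 (adjusted p = 0.0165), with Cldn3 at -2.43, Cldn7 at -1.20 and Cldn1 at -0.72. Genes with the stem Epb were lower in 5 of 8 (adjusted p = 0.0341), the 5 being Epb41l genes, with Epb41l2 at -1.79. Collagens were higher in 10 of 29 (adjusted p = 0.00878), with the basement membrane chains Col4a1 at 1.24 and Col4a2 at 1.15. Clustered protocadherins of the Pcdhb family, on chromosome 18, were higher in 7 of 13 (adjusted p = 0.00554), with Pcdhb20 at 1.87 and Pcdhb14 at 1.69. The prolactin family on chromosome 13 had 4 of 6 members higher and missed the threshold (adjusted p = 0.0545), with Prl2c3 at 1.45 beside Prl8a9 and Prl8a1.

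Other genes that changed in keratinocytes lay in lists that did not pass as a whole, such as fibroblast and collagen matrix genes (camera adjusted p = 0.0507) and matrix metalloproteinases (camera adjusted p = 0.478). Col12a1 had 227 ± 9.25 CPM in transgenic cultures against 106 ± 11.9 CPM (n = 3 each). The macrophage elastase Mmp12 rose by 2.60 and Mmp10 by 2.58 on the log2 scale. Arginase 1, encoded by Arg1, fell by 1.69, Cd28 by 3.02 and the stress keratin Krt17 by 0.47. Lyz2 rose by 3.99, from 0.167 ± 0.054 to 2.65 ± 0.46 CPM. The transgenic skin library with the most Vgll3 (replicate 2, 778 CPM) had the lowest score of the 4 transgenic libraries for T cells (2.492), MHC class I (7.085) and cytokines (1.674), but not for plasma cells (3.643) or neutrophils (0.623), and the highest for hair follicle (4.233).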
